A study of Mus musculus with 24 samples.

How the data were processed

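Messenger RNA was measured in 24 libraries of primary mouse cortical neurons, 4 for each of 2 genotypes (wild type, and H2be knockout with an mCherry knock-in) under 3 conditions (control, BDNF for 30 min, BDNF for 24 h). Per the labels, polyadenylated RNA was isolated with a column kit and libraries were made with a stranded TruSeq mRNA kit. The authors deposited raw whole-number counts of reads per gene, 1 column per library, with no normalisation. The labels name STAR 2.7.9a for alignment, the mm10 assembly, and DESeq2 1.38.3, limma 3.54.2 and edgeR 3.40.2. The program that counted the reads, its strand setting, its treatment of reads shared between genes, and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as histone genes, can therefore not be told apart with certainty.

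The table held 45792 genes as Ensembl identifiers. Symbols and coordinates were taken from GENCODE release M21 on mm10 by the identifier without its version. This named 45229 genes (98.8%), and the other 563 held 0.066% of the counts. All 24 columns were used. Library totals were 19780486 to 62135270 counts. Intervals on ratios of summed counts are 95% exact intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

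Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (a count of 10 scaled to the library size in at least the smallest group, total of at least 15), which left 16777. Libraries were scaled by TMM factors, which ran from 0.824 to 1.07. A single quasi-likelihood model with 1 mean per group over all 24 libraries had 18 residual degrees of freedom and a biological coefficient of variation of 23.5%. Contrasts gave the BDNF response at 30 min and 24 h in each genotype, KO against WT under each condition, and the difference between the genotypes in each response. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed, and SE is the log2 fold change divided by the square root of F. Levels are CPM with TMM factors, and log2 CPM used a prior count of 2. For named genes with 10 or fewer counts in all 4 libraries of a group, the CPM ratio of the summed counts replaces the fitted fold change.

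The size of a response per culture was the mean over a set of genes of log2 CPM in the BDNF library minus that in the control library of the same culture. It was compared between 4 KO and 4 WT cultures by an exact two-sided permutation test over the 70 assignments. The sets were the rapid genes at 30 min, the late genes at 24 h, and the genes past the threshold in the average response of both genotypes, which favours neither.

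These choices, 24 gene lists (activity-regulated genes, signalling, synapse and channel genes, metabolism, ribosome and mitochondria, cortical layers, other cell types, H2B and sex-linked genes) and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and 8 largest falls of the WT responses, the same genes and the 5 largest of each sign in KO, the 10 largest of each sign for KO against WT, and the 10 largest of each sign for the differences in response. Such genes had an adjusted p under 0.05 and a mean of at least 1 CPM, and, except for the differences, all 4 libraries of one group beyond all 4 of the other, with predicted gene models passed over. Up to 4 members of each list with the largest change were added, and Hist2h2be, Bdnf and Ntrk2 always. Genes of a difference in response are also named where their response in the other genotype or their starting level is given. Lists were tested with camera on voom-weighted values from limma 3.58.1 with a preset inter-gene correlation of 0.01 and again with an estimated correlation, Benjamini-Hochberg adjusted over the 24 lists of a contrast. Calls that held both ways were the rapid and the MAP kinase feedback genes in WT at 30 min, the rapid genes in KO at 30 min, and the rapid genes in the difference at 30 min. Another 3 lists (striatal markers, heat shock genes, integrins and laminins) were chosen after the data were seen.

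The descriptions of the libraries carry a culture code shared by the 3 libraries of a replicate within a genotype, and Xist and Y-linked reads matched within each code except for the library labelled KO 24 h replicate 4. Deviations from group means correlated at 0.046 to 0.46 between libraries of a code, over 0.1 in 22 of 24 pairs, and both lower pairs involved KO 30 min replicate 3. The code thus pairs libraries within a genotype, so blocked counts are printed where they moved by over 1.5 times. Between genotypes libraries share only a number.

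The model was tested on simulated data with changes placed in part of the genes at the depths and group sizes of the real libraries. For the WT 24 h contrast it recovered 30%, 61.2% and 85.7% of genes changed 1.5-, 2- and 4-fold, with 7 false calls among 16314 unchanged genes. For KO against WT controls it recovered 22%, 58.6% and 73.9% with 5 false calls among 16295, and for the difference at 30 min 8.33%, 34.3% and 62.7% with 3 among 16259. In this setting a difference in response was thus found less often than a response of the same size. Counts were drawn independently with a single dispersion per gene, without culture differences, correlated genes or libraries that stand apart. The rates therefore do not describe the real KO contrasts, which hold libraries that stand apart.

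Alternatives were DESeq2 1.42.0 size factors in the edgeR fit, the DESeq2 Wald test, limma-voom, no filter and a stricter filter on low counts, the culture or replicate number as a block, the numbering set of the libraries as a covariate, either numbering set alone (set 1 holds 2 WT cultures and 1 KO culture), the compared groups alone, and each library left out in turn. For response sizes they were prior counts of 0.5 and 5, medians, the genotype's control mean, set 2 alone, and each culture left out. Fits without KO culture 4 and KO 30 min replicate 3, blocked fits without KO culture 4 or its 24 h library, and response sizes without KO cultures 3 and 4 (30 min) or KO culture 4 (24 h), were added after the data were seen. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.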

Results

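The series measured messenger RNA by sequencing in primary cortical neurons, taken from E16.5 mouse embryos and grown for 12 days. The neurons were wild type (WT) or carried a knockout of the histone variant gene H2be with an mCherry reporter knocked in (KO). H2BE is a variant of histone H2B, one of the proteins around which DNA is wrapped. BDNF, brain-derived neurotrophic factor, is a secreted ligand of the receptor kinase TrkB, encoded by Ntrk2, and switches on activity-regulated genes in neurons. Each genotype was left untreated (control) or treated with BDNF for 30 min or 24 h, with 4 libraries in each of the 6 groups. The 24 libraries held 19780486 to 62135270 counts each over 45792 genes, of which 16777 passed the filter on low counts and were tested. Values are mean ± SD of CPM (counts scaled by the normalised library size, n = 4 libraries), or log2 fold changes ± SE. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. The comparisons addressed the question named in the study's title, whether H2BE controls activity-dependent gene expression.

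The targeted gene, Hist2h2be (newer symbol H2bc21, ENSMUSG00000068854.7), lies on chromosome 3 from 96221119 to 96223738 in the mm10 assembly. Its counts were higher, not lower, in the KO libraries. In WT it stood at 5.04 ± 0.53 CPM in control, 4.04 ± 0.34 at 30 min and 3.28 ± 0.10 at 24 h. In KO it stood at 55.7 ± 4.58, 56.4 ± 4.49 and 46.4 ± 17.4 CPM. The log2 fold change of KO over WT was 3.46 ± 0.21 in control cultures (adjusted p = 4.37e-10). The counts cover the whole annotated gene, and which part of it the knock-in allele keeps is not given in the sources used here. They therefore separate the genotypes without checking the deletion. Every KO library but 1 lay between 50.0 and 63.1 CPM, and every WT library was at or under 5.83 CPM. The library labelled KO 24 h replicate 4 lay between them at 21.25 CPM. In WT the gene fell at 24 h of BDNF by 0.62 ± 0.20 on the log2 scale (adjusted p = 0.0332).

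Some KO libraries stood apart in other measures. Mitochondrially encoded genes took 4.18% to 6.40% of the counts in WT libraries and 4.20% to 5.77% in KO cultures 1 and 2. They took 7.52% to 9.34% in KO culture 3, and 18.5%, 21.7% and 10.9% in the control, 30 min and 24 h libraries of KO culture 4. KO 30 min replicate 3 had the fewest counts, 19780486, and the fewest genes with a count, 15323. The library labelled KO 24 h replicate 4 also held Xist, which is expressed in females, at 145 CPM together with the Y-linked Ddx3y at 66.3 CPM, while in each of the other 23 libraries the lower of these genes was at or under 8.19 CPM. Counts of changed genes are therefore also given without KO culture 4 and without KO 30 min replicate 3, a choice made after these values were seen.

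**Figure D1:**
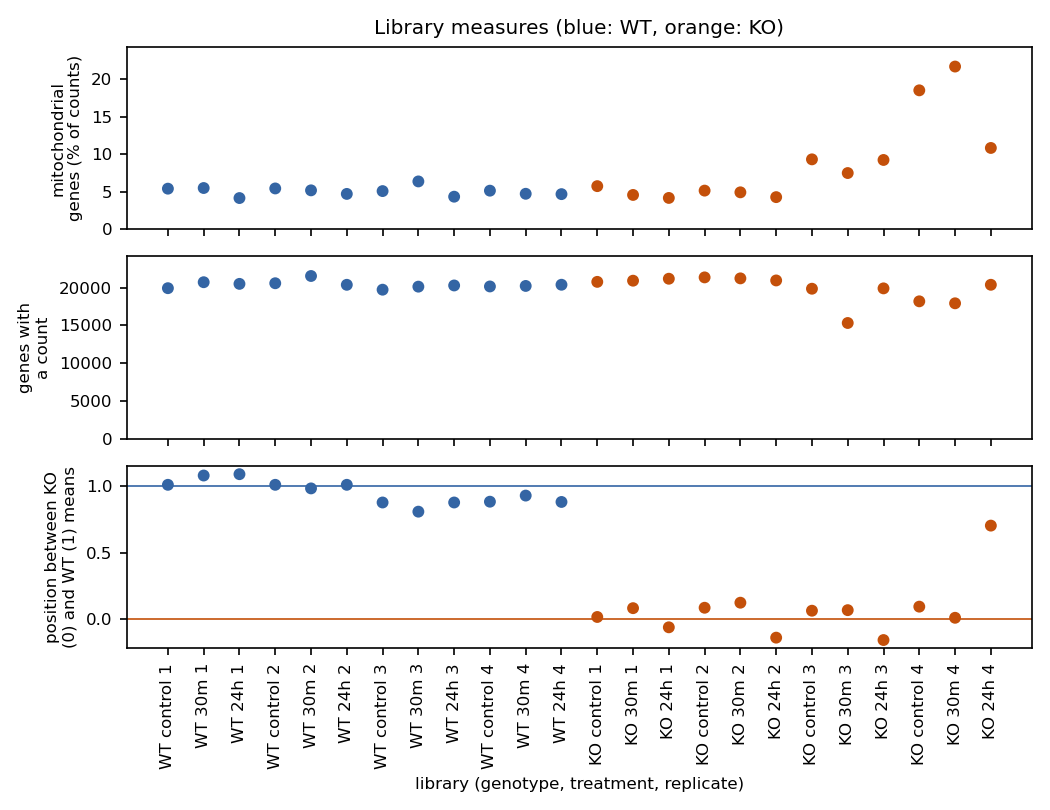
Share of counts from mitochondrially encoded genes (percent), genes with a count, and median position between the KO (0) and WT (1) means of the other libraries of the same condition, over genes that separate the genotypes, in each of the 24 libraries, one point per library, WT in blue and KO in orange. KO culture 4 reached 21.7% mitochondrially encoded counts at 30 min, and its 24 h library lay at 0.703, between the other KO libraries and the WT libraries.

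BDNF for 30 min raised immediate early genes in WT neurons. The largest rises were in Egr2 (6.38 ± 0.41, adjusted p = 4.38e-10), Arc (6.0 ± 0.41) and Fosb (5.94 ± 0.36). Egr2 encodes a zinc finger transcription factor, Arc a synaptic protein that regulates AMPA receptor traffic, and Fosb a component of the AP-1 transcription factor. Egr1, on chromosome 18 from 34859823 to 34864984, went from 35 ± 10.9 to 1175 ± 35.9 CPM. The other genes with the largest rises were Egr4 (5.33 ± 0.39), Ccn1 (5.25 ± 0.48), Egr1 (5.07 ± 0.38), Btg2 (4.92 ± 0.32), Junb (4.42 ± 0.35), Npas4 (4.34 ± 0.52), Ier2 (4.03 ± 0.28), Egr3 (3.99 ± 0.35) and Fos (3.97 ± 0.34). In all, 62 genes rose and 0 fell, while 303 genes had an unadjusted p under 0.05. Chance alone gives about a share of 0.05 of the genes tested, and 303 is less than that. The fit has no term for the culture, so differences between cultures enter its spread.

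Of the 43 measured rapid activity-regulated genes, 28 rose, 0 fell and 15 did not pass the test. Adjusted over the list alone, 36 rose. The list rose against all other genes (adjusted p = 1.16e-08 with an estimated correlation). The list of 23 feedback inhibitors of MAP kinase signalling, the cascade that TrkB activates, also holds the transcription factor genes Etv4 and Etv5. It shares Dusp1 with the rapid list and Rgs2 with the late list. Of its genes 4 rose and 19 did not pass, with 8 past the threshold adjusted over the list alone. They were the phosphatase genes Dusp1 (2.85 ± 0.23), Dusp6 (1.81 ± 0.19) and Dusp5 (1.77 ± 0.21), and Errfi1 (0.63 ± 0.12). The adjusted p of that list was 0.00537 with an estimated correlation. Of the 44 late activity-regulated genes, 1 rose, the kinase gene Plk2 (0.74 ± 0.08), and 3 when adjusted over the list alone, with adjusted p = 0.194 with an estimated correlation. The astrocyte marker Sox9 rose (1.88 ± 0.32, adjusted p = 0.00155), and the other 13 measured astrocyte markers did not pass. The cholesterol biosynthesis list passed with the preset correlation, with 0 of 25 members past the threshold over all genes, and had adjusted p = 0.998 with an estimated correlation. With the culture as a block, 98 genes were called, and without KO culture 4 and KO 30 min replicate 3, 88. The cultures of set 2 alone, defined by the numbering of the libraries, gave 25.

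In KO neurons the same treatment raised 21 genes, led by Egr1 (4.22 ± 0.37, adjusted p = 8.75e-07), Arc (4.09 ± 0.38) and Egr2 (3.77 ± 0.37). Ccn1 (3.26 ± 0.44) and Btg2 (2.94 ± 0.29) followed. No gene fell, and 722 genes, under the share that chance alone gives, had an unadjusted p under 0.05, while DESeq2 called 29 genes, of which 3 fell. The other genes named for WT were Egr4 (2.87 ± 0.35), Ier2 (2.60 ± 0.27), Fosb (2.58 ± 0.31), Egr3 (2.58 ± 0.35), Npas4 (2.33 ± 0.47), Junb (2.19 ± 0.32) and Fos (1.91 ± 0.31), and all of them rose. Egr1 went from 24.9 ± 4.03 to 463 ± 173 CPM. Of the 43 rapid genes, 15 rose and 28 did not pass, with 24 past the threshold adjusted over the list alone (adjusted p = 3.48e-05 with an estimated correlation). Among the MAP kinase feedback genes, Dusp1 (1.53 ± 0.22) and Dusp6 (0.97 ± 0.19) rose, with adjusted p = 0.467 for the list with an estimated correlation, and its call with the preset correlation ended without KO control replicate 4. Plk2 (0.53 ± 0.08) was the 1 late gene that rose, and that list also had adjusted p = 0.467 with an estimated correlation. Its call with the preset correlation ended without KO 30 min replicate 4, and its direction turned without KO culture 4 and KO 30 min replicate 3. KO 30 min replicate 4 held transcripts of the 24 h libraries. Serpinb2 stood at 7.59 CPM and Tm4sf1 at 8.67 CPM in it, and at no more than 0.746 and 0.411 CPM in the other 30 min libraries. No oxidative phosphorylation gene passed, and that list passed with the preset correlation only (adjusted p = 0.987 with an estimated correlation), a call that ended without KO control replicate 1, 2 or 3 or KO 30 min replicate 3 and turned direction without KO 30 min replicate 4. Without KO culture 4 and KO 30 min replicate 3, 19 genes rose.

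The rise of the rapid genes at 30 min was smaller in KO than in WT neurons. Averaged over the 43 genes, the rise above the control library of the same culture was 2.31 ± 0.21 log2 units in WT and 1.18 ± 0.15 in KO (SD, n = 4 cultures per genotype). The KO rise was 50.9% of that in WT, and the difference was -1.14. All 4 KO cultures lay below all 4 WT cultures, and the exact two-sided permutation test gave p = 0.0286, the smallest p that the 70 ways of assigning 4 of 8 cultures allow. The rise was smaller in KO for 38 of the 43 genes (88.4%). Over the 58 genes that rose in the average of both genotypes, chosen without favouring either, the rise was 2.24 ± 0.18 in WT and 1.07 ± 0.11 in KO, a difference of -1.17 (exact permutation p = 0.0286).

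Tested gene by gene in the fit with no term for the culture, 8 genes rose less in KO, all by more than 1 log2 unit, and 0 rose more. They were the AP-1 gene Fosb (-3.36 ± 0.43, adjusted p = 0.000547), Egr2 (-2.61 ± 0.49), the stress-inducible Gadd45b (-2.38 ± 0.36), Arl4d (-1.46 ± 0.23), the Polycomb gene Cbx8 (-1.25 ± 0.22), the heat shock co-chaperone gene Dnajb1 (-1.2 ± 0.14, adjusted p = 0.000247), the antiproliferative gene Tob1 (-1.16 ± 0.21) and Fbxo33 (-1.16 ± 0.20). In KO, Gadd45b (0.51 ± 0.25), Dnajb1 (0.45 ± 0.10), Fbxo33 (0.30 ± 0.14), Arl4d (0.24 ± 0.16) and Cbx8 (0.00 ± 0.15) did not pass the test, while in WT all of them rose by at least 1.26. Fosb already stood higher in untreated KO cultures, at 19.1 ± 2.37 against 3.89 ± 1.2 CPM, and reached 115 ± 34.8 CPM in KO and 239 ± 33.9 CPM in WT. Egr4 (-2.46 ± 0.48), Junb (-2.23 ± 0.44), Btg2 (-1.97 ± 0.39) and Fos (-2.07 ± 0.43) did not pass in the fit with no term for the culture, with adjusted p from 0.0572 to 0.0782. Egr1 differed by -0.85 ± 0.46 and was not past the threshold. In the rapid list 4 genes differed, 24 when adjusted over the list alone, and the list as a whole rose less (adjusted p = 0.000164 with an estimated correlation). The MAP kinase feedback genes had a mean difference of -0.31 (adjusted p = 0.312 with an estimated correlation) and the astrocyte markers one of -0.64 (adjusted p = 0.916 with an estimated correlation).

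The count of 8 became 30 with the culture as a block, 24 with DESeq2 (23 lower and 1 higher in KO) and 0 in set 2 alone, and was also 8, with 5 genes in common, without KO culture 4 and KO 30 min replicate 3, while 301 genes, under the share that chance alone gives, had an unadjusted p under 0.05. It fell to 4 without WT control replicate 1 or 2, WT 30 min replicate 4 or KO control replicate 3, to 5 without KO control replicate 1 or 2 or KO 30 min replicate 3 or 4, and rose to 13 without KO 30 min replicate 2. Dnajb1, Fosb, Gadd45b and Arl4d kept their calls whichever of the 16 libraries was left out, and Egr2 lost its call in 13 of those 16 fits, Tob1 in 10, Cbx8 in 8 and Fbxo33 in 4.

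**Figure D2:**
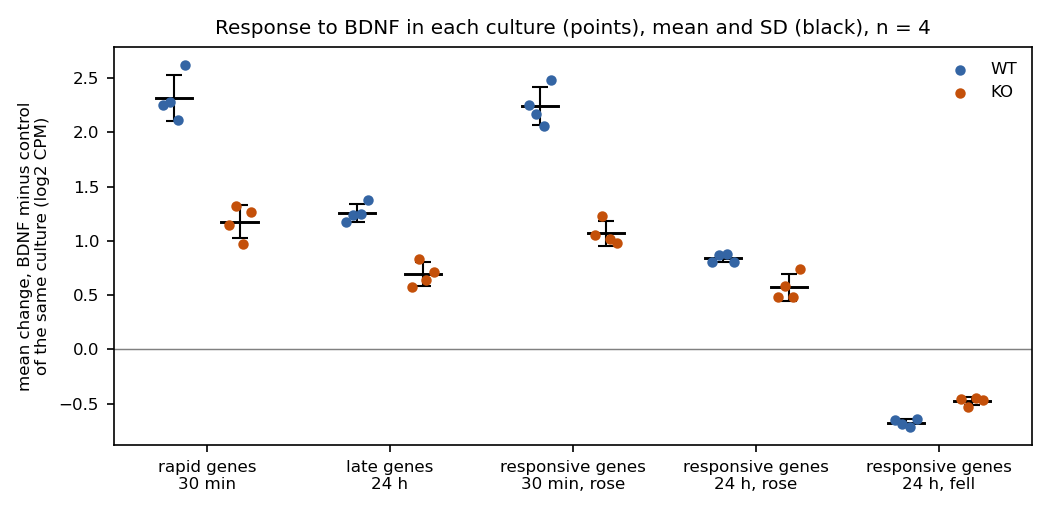
Mean change in log2 CPM between the BDNF and the control library of the same culture, one point per culture, with mean and SD in black (n = 4), for the rapid genes at 30 min, the late genes at 24 h, and the genes that rose or fell in the average response. No KO culture overlapped the WT cultures in any of the 5 measures. The rapid genes rose by 2.31 ± 0.21 in WT and 1.18 ± 0.15 in KO.

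At 24 h BDNF changed the level of 3133 genes in WT neurons, of which 1602 rose and 1531 fell. Among the largest rises, Mmp3, a secreted metalloproteinase, went from 2 counts in the 4 control libraries to 1216 at 24 h, a CPM ratio of 583 (95% exact interval 161 to 4820). Sele, which encodes E-selectin, went from 6 to 1030 counts (ratio 165, interval 75.4 to 450), and Hmga2, a chromatin architectural protein, from 10 to 333 (ratio 31.9, interval 17.2 to 67.2). Further large rises were in Ifi209 (7.24 ± 1.21), the protease inhibitor Serpinb2 (6.24 ± 1.09), Tm4sf1 (5.67 ± 1.01), Akr1b8 (5.43 ± 0.57), the galanin receptor Galr1 (5.22 ± 0.62), the integrin Itga2 (4.73 ± 0.67), Fam19a4 (4.71 ± 0.80), Gimap6 (4.70 ± 0.59) and the prostaglandin synthase gene Ptgs2 (4.64 ± 0.56), each with adjusted p of at most 0.00033. The largest falls were in the neurotrophin gene Ntf3 (-3.65 ± 0.77), the neprilysin gene Mme (-2.90 ± 0.35), Col24a1 (-2.88 ± 0.57), Il4ra (-2.83 ± 0.57), Fbxo32 (-2.75 ± 0.50), the adenosine deaminase gene Ada (-2.71 ± 0.34), Synpo2l (-2.47 ± 0.48) and Aldh1a3 (-2.44 ± 0.59). The receptor gene Ntrk2, on chromosome 13 from 58806569 to 59133970, fell by 0.75 ± 0.14, from 706 ± 73.8 to 421 ± 22.9 CPM. Bdnf itself did not pass (0.58 ± 0.30, adjusted p = 0.203).

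Of the 44 late activity-regulated genes, 24 rose and 0 fell over all genes, with 28 past the threshold adjusted over the list alone (27 higher, 1 lower), and adjusted p = 0.0606 with an estimated correlation. They included the neuronal pentraxins Nptx2 (2.63 ± 0.33) and Nptx1 (1.78 ± 0.36) and the scaffold gene Homer1 (1.05 ± 0.13). Of the 23 MAP kinase feedback genes 15 rose and 0 fell, among them Dusp5 (2.21 ± 0.21), Etv4 (1.71 ± 0.31), Spry4 (1.69 ± 0.23) and Etv5 (1.67 ± 0.35), also with adjusted p = 0.0606 with an estimated correlation. Rapid genes were still raised, 20 of 43 with Arc at 3.52 ± 0.37 and Egr2 at 3.36 ± 0.36, with adjusted p = 0.25 for the list with an estimated correlation. Synaptic and channel genes moved in both directions. Of 54 voltage-gated channel genes 3 rose and 15 fell, such as Cacna1g (-1.30 ± 0.16) and Kcnj9 (-1.18 ± 0.13), of 26 GABA synapse genes 2 rose and 9 fell, such as Gabrd (-0.87 ± 0.17), and of 44 presynaptic genes 3 rose and 9 fell, such as Sv2b (-1.29 ± 0.21). Those 3 lists and the ribosomal protein genes (3 of 54 rose) passed with the preset correlation and had adjusted p of 0.67, 0.67, 0.772 and 0.884 with an estimated correlation. The preset calls of all but the channel genes ended without WT 24 h replicate 2 or WT control replicate 3, and those of the GABA and presynaptic genes also without WT 24 h replicate 1. Among 52 glutamate receptor and postsynaptic genes 5 rose and 8 fell, including Grm2 (-2.32 ± 0.41), Grm3 (-1.54 ± 0.27) and Camk2a (-0.89 ± 0.14), and among 33 genes of homeostatic synaptic scaling 7 rose and 9 fell. Neither list passed as a whole, with adjusted p of 0.217 and 0.983. Of the 29 genes of BDNF, its receptors and transducers 1 rose and 7 fell. No list kept its call with an estimated correlation. The count of changed genes was 5298 with the culture as a block, 4945 with the compared groups alone, 5564 without KO culture 4 and KO 30 min replicate 3, and 237 with set 2 alone, where each group keeps 2 cultures.

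In KO neurons 942 genes changed at 24 h, of which 489 rose and 453 fell. The largest rises were in Mmp3 (5.93 ± 1.18), Hmga2 (4.49 ± 0.92), Sele (4.32 ± 0.78), Ifi209 (4.14 ± 0.96) and Fam19a4, which went from 6 to 104 counts (ratio 13.8, 95% exact interval 6.14 to 38.5). Serpinb2 (3.64 ± 0.93), Tm4sf1 (3.32 ± 0.86), Itga2 (3.27 ± 0.61), Akr1b8 (2.92 ± 0.48), Galr1 (2.75 ± 0.54), Gimap6 (2.69 ± 0.53) and Ptgs2 (1.58 ± 0.43) also rose. The largest falls were in the cold-sensing channel gene Trpm8 (-3.00 ± 0.69), Grm2 (-2.41 ± 0.41), Fam181a (-2.32 ± 0.39), the vasopressin receptor gene Avpr1a (-2.24 ± 0.30) and Wnt7a (-2.14 ± 0.60). Of the genes with the largest falls in WT, Mme (-1.80 ± 0.32) and Synpo2l (-1.80 ± 0.44) fell in KO, while Ntf3 (-1.63 ± 0.79) and Aldh1a3 (-1.67 ± 0.74), both already lower in untreated KO than in untreated WT cultures, and Il4ra (-1.04 ± 0.62), Fbxo32 (-0.63 ± 0.48), Ada (-0.62 ± 0.34) and Col24a1 (-0.10 ± 0.55) did not pass. Ntrk2 did not pass either (-0.22 ± 0.14, adjusted p = 0.449), and its difference between genotypes was not past the threshold (0.53 ± 0.20, adjusted p = 0.689).

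Among the late genes 11 of 44 rose in KO at 24 h, including Stc1 (1.90 ± 0.38), Nptx1 (1.80 ± 0.36) and Nptx2 (1.38 ± 0.32). Of the rapid genes 9 of 43 rose and of the MAP kinase feedback genes 4 of 23, including Lrig1 (1.62 ± 0.25) and Dusp5 (1.10 ± 0.20). Each of these 3 lists had adjusted p = 0.313 with an estimated correlation. In these lists 14, 15 and 10 genes, counted in either direction, were past the threshold adjusted over the list alone. The mean log2 CPM of the rapid genes was 4.69 in KO 24 h replicate 4 and at most 4.52 in the other 24 h libraries. Most cholesterol biosynthesis genes did not pass in KO at 24 h, while Sc5d (0.43 ± 0.12) rose, with adjusted p = 0.859 for the list with an estimated correlation, and the list's call with the preset correlation ended without KO control replicate 4 or KO 24 h replicate 4 and turned direction without KO culture 4 and KO 30 min replicate 3. The count of changed genes was 2834 with the culture as a block and 1641 without KO culture 4 and KO 30 min replicate 3. It was 482 and 486 without KO 24 h replicate 2 and 1, 621 without replicate 3, and 601 and 541 without KO control replicate 2 and 4.

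The change from control to 24 h was also smaller in KO. The mean rise of the 44 late genes was 1.26 ± 0.09 in WT and 0.69 ± 0.11 in KO (SD, n = 4 cultures each), 55% of that in WT, with an exact permutation p of 0.0286. The 2108 genes that rose in the average response rose by 0.84 ± 0.04 in WT and 0.57 ± 0.12 in KO, and the 2146 that fell did so by -0.67 ± 0.03 and -0.48 ± 0.04 (exact permutation p = 0.0286 each). Taken as medians over genes the differences between the genotypes were -0.36 for the late genes and -0.17 for the genes that rose, against -0.57 and -0.27 as means. KO culture 4, whose 24 h library held Xist and Y-linked reads together, is among the 4 KO cultures. Without it the mean differences were -0.57 for the late genes, -0.32 for the genes that rose and 0.19 for those that fell, and no p was computed. The levels reached at 24 h were 4.77 ± 0.10 mean log2 CPM in WT and 4.75 ± 0.03 in KO for the genes that rose (exact permutation p = 0.657) and 4.14 ± 0.05 and 4.12 ± 0.04 for those that fell (exact permutation p = 0.6). In control libraries they were 3.94 ± 0.06 and 4.18 ± 0.12, and 4.81 ± 0.03 and 4.598 ± 0.03. The late genes stood higher in KO both in control (5.12 ± 0.12 against 4.15 ± 0.18) and at 24 h (5.82 ± 0.04 against 5.41 ± 0.15). Across all 16777 genes the WT and KO responses at 24 h had a Pearson correlation of 0.618, where genes are not independent replicates.

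Gene by gene, in the fit with no term for the culture, 6 genes differed in their 24 h response. Tox3 (1.45 ± 0.23), the proteoglycan gene Vcan (1.59 ± 0.29), Adgrb3 (0.74 ± 0.12) and B3gat1 (0.72 ± 0.11) had higher values in KO, and the stress-responsive transcription factor gene Atf3 (-1.79 ± 0.31) and the myosin light chain kinase gene Mylk (-1.58 ± 0.28) lower ones, with adjusted p from 0.02 to 0.0348. Vcan fell by 2.31 ± 0.21 in WT and by 0.72 ± 0.20 in KO, and Atf3 rose by 2.86 ± 0.23 and 1.07 ± 0.22. Tox3 fell in WT (-0.83 ± 0.16) and rose in KO (0.62 ± 0.17), as did Adgrb3 (-0.36 ± 0.09 and 0.38 ± 0.09). The KO values include KO 24 h replicate 4, which lay at 0.703 between KO (0) and WT (1). Any WT reads in that library would raise Tox3 and Adgrb3 in KO at 24 h, so their opposite direction is uncertain. Mylk rose in WT (1.14 ± 0.20) and B3gat1 fell (-0.92 ± 0.08), and neither passed in KO (-0.43 ± 0.19 and -0.20 ± 0.08). These genes already differed in untreated cultures, where Tox3 (-1.40 ± 0.17), Vcan (-1.92 ± 0.21), Adgrb3 (-1.16 ± 0.09) and B3gat1 (-0.93 ± 0.08) were lower in KO and Mylk (2.69 ± 0.21) and Atf3 (1.30 ± 0.23) higher. Ptgs2 differed by -3.06 ± 0.69 without passing (adjusted p = 0.176), and it too stood higher in untreated KO cultures. The MAP kinase feedback list had a mean difference of -0.48 with 0 genes past the threshold over all genes and 8 when adjusted over the list alone (adjusted p = 0.0879 with an estimated correlation). The late list had one of -0.62, with 3 genes adjusted over the list alone (adjusted p = 0.182 with an estimated correlation).

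The count of 6 became 299 with the culture as a block (133 higher, 166 lower), 61 with DESeq2, 111 without KO culture 4 and KO 30 min replicate 3, and 0 in set 2 alone, while 940 genes had an unadjusted p under 0.05. It fell to 0 without WT 24 h replicate 2 or 3 or KO control replicate 1, to 2 without WT control replicate 2 or KO 24 h replicate 2 or 3, and rose to 11 without KO 24 h replicate 4, and each of the 6 genes lost its call in at least 3 of the 16 fits that left out 1 library.

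**Figure D3:**
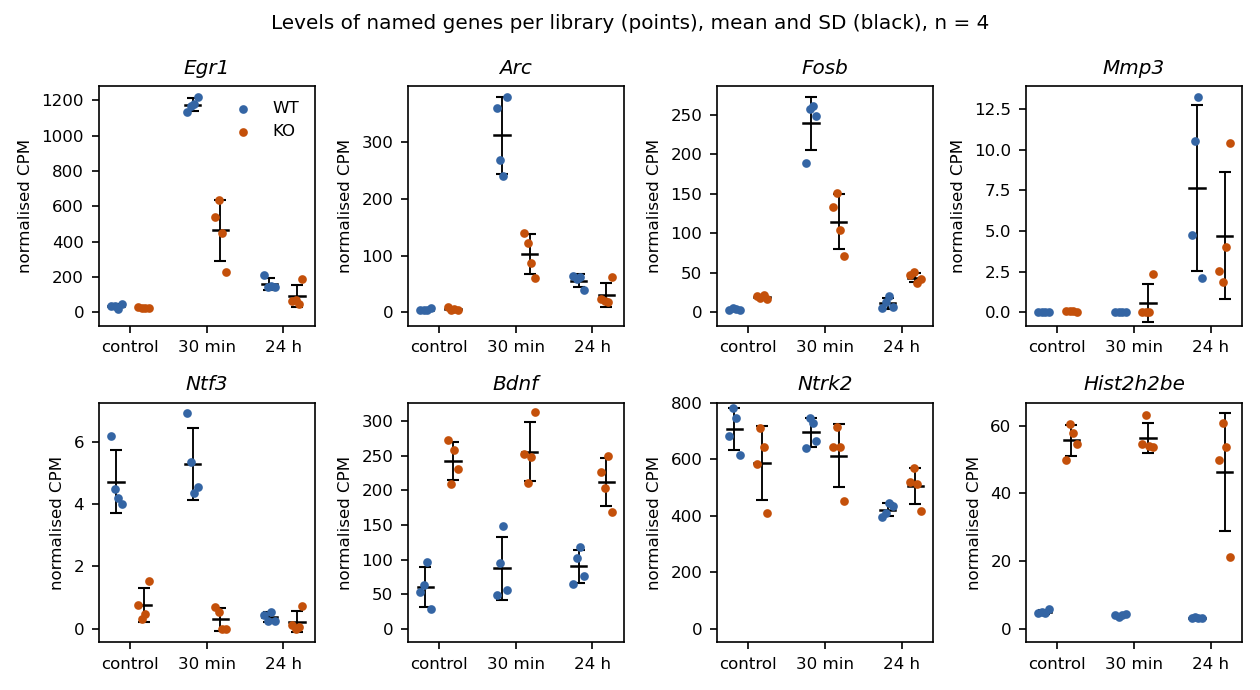
Normalised CPM of Egr1, Arc, Fosb, Mmp3, Ntf3, Bdnf, Ntrk2 and Hist2h2be in each library (points) with mean and SD in black (n = 4), in WT and KO cultures under control conditions and after 30 min and 24 h of BDNF. Egr1 reached 1175 ± 35.9 CPM in WT and 463 ± 173 CPM in KO at 30 min.

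Untreated KO and WT neurons differed in 3592 genes, of which 1903 were higher and 1689 lower in KO. The highest fold changes were in Tnmd (4.71 ± 0.89), Ptgs2 (4.63 ± 0.56), Ppp1r1c (4.58 ± 0.49), Emp1 (3.90 ± 0.55), the heparanase gene Hpse (3.83 ± 0.39), Lce1g (3.73 ± 0.94), Art3 (3.68 ± 0.63), Crisp1 (3.47 ± 0.78), Hist2h2be and the collagen gene Col10a1 (3.39 ± 0.43). The lowest were in Dmrt2 (-4.44 ± 0.96), Aldh1a3 (-4.02 ± 0.66), Prokr1 (-3.95 ± 0.79), Cdhr1 (-3.92 ± 1.06), Abca8a (-3.56 ± 0.41), the caveolin gene Cav1 (-3.51 ± 0.68), Rgs9bp (-3.38 ± 0.49), Dsc3 (-3.14 ± 0.80), Ccbe1 (-3.13 ± 0.49) and Prss35 (-3.13 ± 0.40). Bdnf, on chromosome 2 from 109674700 to 109727007, was higher in KO by 2.01 ± 0.31 (adjusted p = 8.53e-05), at 242 ± 28.0 against 60.3 ± 28.4 CPM. Ntrk2 did not pass (-0.27 ± 0.14, adjusted p = 0.197).

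Of 25 cholesterol biosynthesis genes 22 were lower in KO and 0 higher, including Fdps (-1.63 ± 0.25), Nsdhl (-1.44 ± 0.21), Lss (-1.41 ± 0.22) and Acat2 (-1.35 ± 0.19), with adjusted p = 0.231 with an estimated correlation. Of 43 nuclear-encoded oxidative phosphorylation genes 34 were higher and 0 lower, including Cycs (1.06 ± 0.29), Ndufa5 (1.0 ± 0.35) and Cox8a (0.99 ± 0.24), with adjusted p = 0.241 with an estimated correlation. The share of mitochondrially encoded counts was also higher in the KO controls, at 9.71% ± 6.17 against 5.29% ± 0.18 in WT, through KO controls 3 (9.34%) and 4 (18.5%), since KO controls 1 (5.77%) and 2 (5.175%) were near the WT level, and 0 of the 14 mitochondrially encoded genes passed. Of the late genes 20 of 44 were higher and 0 lower (adjusted p = 0.231 with an estimated correlation), including Ptgs2, Npy (2.90 ± 0.34), Gpr3 (2.09 ± 0.36) and Mmp10, which had 54 counts against 4 (ratio 13.5, 95% exact interval 4.98 to 51.4). Of the MAP kinase feedback genes 11 of 23 were higher, such as Rgs2 (2.0 ± 0.27) and Dusp4 (1.26 ± 0.18), with adjusted p = 0.246 with an estimated correlation. Of the rapid genes 13 were higher and 1 lower, such as Fosb (2.30 ± 0.32) and Npas4 (1.52 ± 0.46), with adjusted p = 0.587 with an estimated correlation. That list's call with the preset correlation ended without WT control replicate 1 or 4 or KO control replicate 1 or 3.

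Markers of cell types also differed. Of 10 deep-layer cortical neuron markers 8 were lower in KO, including Ldb2 (-2.75 ± 0.39), Foxp2 (-2.64 ± 0.60), Tle4 (-2.18 ± 0.39) and Tbr1 (-1.88 ± 0.30), with adjusted p = 0.231 with an estimated correlation. Of 10 upper-layer markers 2 were higher, such as Inhba (1.2 ± 0.38), and 1 lower, Rorb (-1.93 ± 0.38), and the list did not pass (adjusted p = 0.328). Of 23 interneuron markers 12 were higher and 0 lower, including Npy, Pvalb (2.13 ± 0.75), Cck (2.04 ± 0.37) and Maf (1.43 ± 0.40), with adjusted p = 0.532 with an estimated correlation. The mean log2 CPM of this list varied among WT controls (4.59 ± 0.69), and the highest, 5.6, lay within the KO controls (5.38 to 5.66). The highest WT library was also at 5.7 at 30 min and 5.66 at 24 h, where KO libraries reached 5.61 and 5.52. Npy stands in both the late and the interneuron list. Of 14 astrocyte markers 3 were lower, Aldoc (-2.02 ± 0.56), Slc1a2 (-0.92 ± 0.24) and Glul (-0.71 ± 0.15), with adjusted p = 0.532 with an estimated correlation. Of 29 genes of BDNF, its receptors and transducers 1 was higher and 6 lower, including Ntf3 (-2.67 ± 0.73) and the low-affinity receptor gene Ngfr (-1.48 ± 0.42), with adjusted p = 0.55 with an estimated correlation. That call with the preset correlation ended without WT control replicate 3 or KO control replicate 4.

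The remaining lists did not pass in untreated cultures. Glutamate receptor and postsynaptic genes were higher in 8 and lower in 12 of 52 cases, scaling genes in 5 and 8 of 33, presynaptic genes in 9 and 10 of 44, GABA synapse genes in 8 and 5 of 26, and voltage-gated channel genes in 13 and 14 of 54. Among microglia markers 2 of 11 were higher, Csf1r (3.08 ± 0.77) and Laptm5 (1.87 ± 0.64). Oligodendrocyte lineage markers had 1 higher (Lhfpl3, 0.77 ± 0.21) and 1 lower (Mog, -0.98 ± 0.20) of 9, fibroblast and meningeal markers 1 higher (Mgp, 2.15 ± 0.72) and 1 lower (Fbln1, -1.52 ± 0.33) of 11, and dividing cell and progenitor markers 1 lower of 16, Hes1 (-2.16 ± 0.38). Of the 4 measured H2B genes Hist2h2be was the 1 that passed, and 0 of 54 ribosomal protein genes, 0 of 7 endothelial and mural markers and 0 of 5 sex-linked genes passed. Counts of the near-identical histone genes are uncertain, since how reads shared between copies were counted is not given in the sources used here. The count of genes that differed was 5326 without KO culture 4 and KO 30 min replicate 3, and 599 with set 2 alone, in which 40.6% were higher in KO.

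At 30 min of BDNF 4760 genes differed between KO and WT, of which 2452 were higher and 2308 lower in KO. The largest differences included Ifi209 (5.99 ± 1.17), Lce1g (4.74 ± 0.92), Tnmd (4.73 ± 0.88), the melatonin receptor-like Gpr50 (4.6 ± 0.68), Hpse (4.36 ± 0.39), Ppp1r1c (4.14 ± 0.47), Sim1 (3.83 ± 0.65) and Col10a1 (3.80 ± 0.42). Art3 had 322 counts against 10 (ratio 41.1, 95% exact interval 22.1 to 86.5). Lower genes included Aldh1a3 (-4.08 ± 0.66), Abca8a (-4.05 ± 0.42), Cdhr1 (-3.90 ± 1.07), Ntf3 (-3.82 ± 0.77), Zic1 (-3.77 ± 0.94), Dmrt2 (-3.59 ± 0.92), Ccbe1 (-3.35 ± 0.50), Lhx1 (-3.33 ± 0.77) and Foxp2 (-3.27 ± 0.62), and Kcnj5 had 10 counts against 394 in WT (ratio of WT to KO 30.9, interval 16.6 to 64.9). Of the 43 rapid genes 24 were lower and 1 higher in KO, including Klf4 (-3.00 ± 0.65), Egr3 (-2.35 ± 0.33), Egr2 (-2.22 ± 0.33) and Btg2 (-1.93 ± 0.27). Late genes were higher in 21 of 44 cases, cholesterol biosynthesis genes lower in 22 of 25, oxidative phosphorylation genes higher in 37 of 43 and deep-layer markers lower in 9 of 10. Each of these 5 lists had adjusted p = 0.197 with an estimated correlation. Interneuron markers were higher in 11 and lower in 1 of 23 cases (adjusted p = 0.54 with an estimated correlation), and astrocyte markers lower in 10 of 14, such as Gja1 (-2.62 ± 0.62) and Aldoc (-2.57 ± 0.59) (adjusted p = 0.42 with an estimated correlation). Mmp3 was higher in KO, with 54 counts against 2, almost all of them in KO 30 min replicate 4. The count of genes was 2688 with the compared groups alone, 4771 without KO culture 4 and KO 30 min replicate 3, and 957 with set 2 alone.

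At 24 h of BDNF 2223 genes differed, of which 1189 were higher and 1034 lower in KO. The largest differences included Col10a1 (4.13 ± 0.42), Hist2h2be (3.82 ± 0.21), Ppp1r1c (3.52 ± 0.45), Tnmd (3.32 ± 0.80), Hpse (3.24 ± 0.38), the aggrecan gene Acan (3.12 ± 0.62), Nrap (3.10 ± 0.64), Tbx2 (2.97 ± 0.61) and Sgcz (2.69 ± 0.30). The lowest were in Filip1l (-2.17 ± 0.36), Fam19a4 (-2.11 ± 0.67), Ldb2 (-1.98 ± 0.38), Plekhd1 (-1.97 ± 0.59), Stra6 (-1.94 ± 0.50), Synpo2 (-1.77 ± 0.38), Kif26a (-1.76 ± 0.26), Mei4 (-1.72 ± 0.39), Samd9l (-1.68 ± 0.56) and Krt77 (-1.68 ± 0.53). The rule for named genes passes over those in which KO 24 h replicate 4, at 0.703 toward WT, overlapped the WT libraries. Without that library 43 genes were over 4-fold higher and 28 over 4-fold lower in KO with no overlap. With another 24 h library left out instead, these were at most 37 and 4. Fold changes and list counts in this paragraph include KO 24 h replicate 4. Bdnf was higher in KO (1.23 ± 0.31, adjusted p = 0.00958). Cholesterol biosynthesis genes were lower in 20 of 25 cases (adjusted p = 0.221 with an estimated correlation), oxidative phosphorylation genes higher in 18 of 43 and deep-layer markers lower in 6 of 10 (both adjusted p = 0.313 with an estimated correlation). Interneuron markers were higher in 6 of 23 cases (0.607), late genes higher in 10 and lower in 1 of 44 (0.572), and GABA synapse genes higher in 7 and lower in 2 of 26 (0.313), where each value in brackets is the adjusted p with an estimated correlation. The H2B genes (2 of 4 higher, adjusted p = 0.182), astrocyte markers (1 higher and 1 lower of 14, adjusted p = 0.572) and microglia markers (1 of 11 higher, adjusted p = 0.391, both with an estimated correlation) also passed with the preset correlation. The call for the astrocyte markers ended without WT 24 h replicate 4.

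The count of 2223 rose to 5435 without KO culture 4 and KO 30 min replicate 3 and fell to 11 in set 2 alone, where 90.9% were higher in KO. It was 1278 without WT 24 h replicate 1, and 1243, 1267 and 1216 without KO 24 h replicate 1, 2 and 3. Across all genes, the KO to WT log2 fold changes correlated between control and 30 min (Pearson 0.755), control and 24 h (0.68) and 30 min and 24 h (0.63). These comparisons come from different libraries of the same 8 cultures, so the values are not independent.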

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

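The tests of a mixing that also reached KO 30 min replicate 4, of a higher starting level of the rapid genes and of a shifted start at 24 h, and the splits with a term per culture, were chosen after the results were seen, as was the list of striatal markers, and the other tests of explanations in this part were set before their results were seen.

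In all, 12 values lay far from the other 3 libraries of their group by Dixon's ratio, among 82 groups of 4 that were examined, where chance gives about 1 in 20. The mitochondrially encoded share was 21.7% in KO 30 min replicate 4, and the ribosomal protein share was 2.35% in KO control replicate 4 and 1.9% in the library labelled KO 24 h replicate 4. Hist2h2be stood apart in WT control replicate 4 (5.83 CPM) and KO 30 min replicate 2 (63.1 CPM). Egr1 did so in WT 24 h replicate 1 (209 CPM) and KO 24 h replicate 4 (187 CPM), and in the latter so did Arc (61.5 CPM) and Ntf3 (0.719 CPM). Mmp3 stood apart in WT control replicate 2 (0.044 CPM), WT 30 min replicate 1 (0.0443 CPM) and KO 30 min replicate 4 (2.35 CPM), the first and second of which are a few counts against 0.

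Of these 12 values, 6 belong to the 30 min and 24 h libraries of KO culture 4. The library labelled KO 24 h replicate 4 held Xist and Y-linked reads together, so reads of a wild-type male culture may have been mixed into it. Between the mean of the other KO libraries (0) and the WT mean (1), its median position over all genes that separate the genotypes was 0.703, while no other KO library exceeded 0.123 and no WT library was under 0.808. Over the 43 genes higher in KO it was also 0.703, where other KO libraries reached 0.338 and WT libraries were at 0.884 or above. Over the 28 genes lower in KO it was 0.71, above the other KO libraries (at most 0.0745) but inside the range of the WT libraries, which began at 0.587. Both of these limits come from control and 30 min libraries, since the other 24 h libraries had too few such genes for a median. An exchange of the whole library is argued against, since the third quartile of its position was 0.804, short of the 0.9 an exchange needs, and the control library of the culture was in place. A mixing that also reached KO 30 min replicate 4 remains open, since that library lay at 0.646 over 28 genes of 24 h and 0.629 over 22 genes of 30 min on the way from the other KO 30 min libraries to the 24 h libraries, where the other 30 min libraries were at or under 0.189 and 0.445. On the same scale KO 24 h replicate 4 lay at 0.73 over the genes of 30 min, where the other 24 h libraries were at 0.977 or above. No biological explanation was tested, and each count is also given without the culture and KO 30 min replicate 3.

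Genes whose response to BDNF differed between the genotypes by edgeR's quasi-likelihood test of the difference were, at 30 min, Fosb (-3.36), Egr2 (-2.61), Gadd45b (-2.38), Arl4d (-1.46), Cbx8 (-1.25), Dnajb1 (-1.20), Tob1 (-1.16) and Fbxo33 (-1.16), and at 24 h Vcan (1.59), Tox3 (1.45), Adgrb3 (0.74), B3gat1 (0.72), Mylk (-1.58) and Atf3 (-1.79), all in log2 units of KO minus WT. The sizes of the response per culture differed by -1.14 for the rapid genes at 30 min, -0.57 for the late genes at 24 h, -1.17 for the genes that rose at 30 min, and -0.27 and 0.20 for those that rose and fell at 24 h (exact permutation p = 0.0286 each). The smaller changes at 24 h go with a shifted starting level, as the score of the 24 h response was 0.46 higher in KO control libraries and differed by -0.0076 at 24 h, so a shifted start is not excluded for them. Gene lists whose mean response differed with a preset correlation were, at 30 min, the rapid genes (-1.13), the MAP kinase feedback genes (-0.31) and the astrocyte markers (-0.64). At 24 h they were the rapid (-0.28), late (-0.62), MAP kinase feedback (-0.48), presynaptic (0.12), voltage-gated channel (0.17), cholesterol biosynthesis (0.22) and oxidative phosphorylation genes (-0.21). With an estimated correlation the rapid genes at 30 min passed (adjusted p = 0.000164) and the other 9 did not, with adjusted p from 0.0879 to 0.916. The 24 h calls of the presynaptic, channel, cholesterol and oxidative phosphorylation lists ended or turned without KO control replicate 4, those of the presynaptic and cholesterol lists also without several other single libraries, and that of the astrocyte markers at 30 min without any of 5 libraries of WT or KO.

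The smaller rise of the rapid genes in KO at 30 min was set against 2 technical or trivial accounts. A higher starting level with the same level reached is argued against, since the mean log2 CPM of these genes at 30 min was itself lower in KO by 0.85, from 5.79 ± 0.14 in WT to 4.94 ± 0.27 in KO (KO minus WT -0.8527, exact permutation p = 0.0286), while the control levels were 3.48 ± 0.20 and 3.76 ± 0.31 (exact permutation p = 0.2). A higher start could still give part of the smaller rise, since 3 of the 4 KO controls lay above the highest WT control, with a mean difference of 0.28. KO cultures 3 and 4, whose libraries stand apart, are not needed for the smaller rise, since KO cultures 1 and 2 alone gave -1.08, 95% of the difference, both below all 4 WT cultures. The controls of KO cultures 1 and 2 stood at 3.98 and 3.85, above every WT control, so the same limit holds for them. These values are consistent with a genotype effect on the rapid response as a hypothesis, although how the cultures of each genotype were prepared remains untested. With no term for the culture, other splits of the 8 cultures gave at most 0 genes at 30 min against 4 in the real split of the compared libraries, and at most 0 at 24 h against 9 (1 of 35 splits each). Differences in starting level between cultures widen the spread in those other splits, so nothing is concluded from them. The splits with a term per culture used the compared libraries alone, where the blocked fit of all 24 libraries gave 299 genes at 24 h. Their real split gave 30 genes at 30 min and 349 at 24 h, and the others at most 0 and 14. In each case 1 of 35 splits, the real one, reached the real value. That is the smallest share that 35 splits allow, not adjusted over the counts, so it makes chance unlikely without excluding it.

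The 3592 genes that differed between untreated KO and WT cultures had no counterpart in other splits, where at most 5 genes were called against 3410 in the real split of the compared libraries (1 of 35). Those other splits mix the genotypes, which widens their spread, so nothing is concluded from their low counts. Striatal cells carried into the KO cultures are argued against, since the striatal markers had a median KO minus WT log2 fold change of -0.64, with 15 of 20 genes under 0 and quartiles of -1.11 and -0.13. Striatal cells in the WT cultures would lower these markers in KO relative to WT, and this was not tested. Sequence linked to the targeted locus that acts on nearby genes would raise the share of called genes there. Within 20 Mb 91 of 415 tested genes were called (21.9%) against 21.5% of 15185 on the other autosomes. The odds ratio was 1.03 with a 95% interval of 0.802 to 1.3 (Fisher's exact test, p = 0.809), which argues against a large local excess. Linked sequence that changes genes elsewhere would leave these shares alike, so the test cannot decide on it. The uneven spread of the genotypes over the numbering sets is argued against too, since the log2 fold changes in set 2 alone were a median of 0.99 times those in all libraries (quartiles 0.877 and 1.11), with the same sign for 100% of 3589 genes. These genes were chosen in all libraries, which include the 3 KO and 2 WT cultures of set 2, so the ratio and the shared sign are partly built in. With the set as a covariate 3480 genes were called, 3344 of them in common, and set 2 alone called 599, of which 40.6% were higher in KO. Genotype itself remains a hypothesis, and cell makeup, litter and preparation, which the design ties to genotype through the cultures, stay open and untested.

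For the other counts between genotypes, 1 of 35 splits reached the real value at 30 min (2688 genes, at most 4 in others) and at 24 h (2464, at most 561). That is the smallest share that 35 splits allow, and it was not adjusted over the counts. The other splits also mix the genotypes, which widens their spread, so chance is not excluded by their low counts. The split with 561 genes exchanges the fourth replicates of WT and KO at 24 h. For the responses to BDNF, 1 of 35 splits reached the real value in WT at 24 h (4945, at most 4 in others), KO at 30 min (16, at most 5) and KO at 24 h (552, at most 6). In WT at 30 min 3 of 35 splits gave as many genes as the real one (60), so the count alone does not exclude chance. Those other splits, with 425 and 63 genes, set whole cultures against each other (1 and 4 against 2 and 3, and 1 and 2 against 3 and 4, the latter being the numbering sets), a structure of the samples by culture. The culture pairs control and BDNF libraries, so for each of the 4 responses the real split is compared with the 8 splits that part all 4 pairs. The real one alone called any gene in each (highest other 0), and 8 splits are too few for a share under 0.05. The blocked counts were 98 and 5298 for WT at 30 min and 24 h and 25 and 2834 for KO.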

How the results depend on the processing

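Fits without KO culture 4, without KO culture 4 and KO 30 min replicate 3, without KO 24 h replicate 4 in a blocked fit, and without KO cultures 3 and 4 for the response sizes at 30 min were chosen after the data were seen, and the other alternatives before. The 5 response sizes per culture kept their direction in all 75 alternatives. Those that keep all 8 cultures had the same exact permutation p of 0.0286, and those that leave out cultures were not tested against the threshold. Use of the genotype's control mean cannot change the difference. At 24 h the alternative without KO culture 4 repeats the one that leaves out that culture in turn, so these add no evidence. With the median over genes the difference was -0.36 for the late genes (-0.57 with the mean) and -0.17 for the genes that rose at 24 h (-0.27). Of 9037 alternatives over 451 single-gene results, 7962 kept the direction and the call, 1074 kept the direction but lost the call and 1 reversed. Of 757 over 54 gene list results 654 kept both, 97 kept the direction but lost the call and 6 reversed. Of 199 alternatives over the 9 counts of changed genes 132 stayed within 1.5 times, and the others follow. Calls lost with fewer libraries go with fewer samples, and for the other changes the cause was not tested.

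With the culture as a block within a genotype, for which the pairing is given with the methods, the counts were 98 for WT at 30 min (62 without it), 5298 for WT at 24 h (3133), 25 for KO at 30 min (21), 2834 for KO at 24 h (942), 30 for the difference at 30 min (8) and 299 for that at 24 h (6). No gene list and no named gene that passed lost its call with the block. Blocked and without KO 24 h replicate 4 they were 116, 6154, 3319, 38 and 487 for WT at 30 min and 24 h, KO at 24 h and the differences at 30 min and 24 h, and blocked without KO culture 4 they were 150, 6710, 3270, 41 and 835. Between genotypes libraries share only a number, and deviations of same-numbered libraries correlated at -0.089 to 0.043. The replicate number as a block gave 4227 genes for KO against WT in control, 5442 at 30 min and 2916 at 24 h.

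Set 1 holds 1 KO culture, so each KO group there is 1 library and the spread comes from the WT groups, which makes its KO counts no test of their own. In set 1 alone the counts were 4 for KO at 30 min, 122 for KO at 24 h, 3449 for KO against WT at 24 h and 0 for each difference. In set 2 alone they were 25 and 237 for WT at 30 min and 24 h, 10 and 19 for KO, 599, 957 and 11 for KO against WT in control, at 30 min and at 24 h, and 0 for each difference. With the compared groups alone they were 4945 for WT at 24 h, 552 for KO at 24 h, 2688 for KO against WT at 30 min and 4 for the difference at 30 min. Without KO culture 4 and KO 30 min replicate 3 they were 5564 for WT at 24 h, 1641 for KO at 24 h, 5435 for KO against WT at 24 h and 111 for the difference at 24 h. DESeq2 gave 1509 for KO at 24 h, 24 for the difference at 30 min and 61 for that at 24 h, and with no filter the differences were 15 and 12.

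With each library left out in turn the counts ran from 55 to 63 for WT at 30 min, 2311 to 2839 for WT at 24 h, 14 to 21 for KO at 30 min, 482 to 985 for KO at 24 h, 2667 to 3191, 3620 to 4802 and 1216 to 3138 for KO against WT in control, at 30 min and at 24 h, 4 to 13 for the difference at 30 min and 0 to 11 for that at 24 h. The libraries that moved a count by over 1.5 times are named with the comparisons.

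The result for Mmp3, KO versus WT, 30 min, reversed to -2.97 in set 1 alone, with 1 KO library. Without KO culture 4 and KO 30 min replicate 3 the late genes (-0.083) and oxidative phosphorylation genes (-0.049) reversed in KO at 30 min, and the cholesterol genes in KO at 24 h (-0.066) and in the difference at 24 h (-0.079). The oxidative phosphorylation genes also reversed in KO at 30 min without KO 30 min replicate 4 (-0.114), where the other single libraries left out gave up to 0.223 (without KO control replicate 4), and in the difference at 24 h without KO control replicate 4 (0.044), where the others gave down to -0.206 (without KO control replicate 2). No scaling alternative moved the median of all genes by over 0.1 on the log2 scale. At this depth and with 4 libraries a group, 34.3% of simulated differences in response of 2-fold were recovered, so smaller ones were mostly not detectable in that setting. The simulation held no culture differences and no libraries that stand apart, so its rates do not describe the real KO contrasts.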

Other observations

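The lists and the test in this part were chosen after the data were seen.

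Some integrin and laminin genes moved with BDNF at 24 h in both genotypes. The p-values of the added lists, chosen after the data were seen, describe the lists and are no independent test of them. They were adjusted over 3 lists and cannot be set against those of the 24 lists fixed before. Of 25 integrin and laminin genes 11 rose and 2 fell in WT (adjusted p = 0.0279 over the 3 added lists with an estimated correlation), and 8 rose and 2 fell in KO (adjusted p = 0.0365). At 30 min none of the 25 passed in either genotype, with adjusted p of 0.606 in WT and 0.372 in KO. Heat shock genes rose in 4 of 13 cases in WT at 24 h (adjusted p = 0.0279 with an estimated correlation) and in 2 of 13 in KO (adjusted p = 0.0751). In untreated cultures 5 of 13 heat shock genes were higher in KO (adjusted p = 0.0721 with an estimated correlation), and 5 integrin and laminin genes were higher and 1 lower (adjusted p = 0.385). Neither list differed between the genotypes in its 24 h response, with adjusted p of 0.358 for both.

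A hypothesis is that untreated KO neurons may lie part of the way toward the state that BDNF brings about in 24 h. A score was taken as the mean log2 CPM of the 2108 genes that rose minus that of the 2146 that fell in the average 24 h response, in which the controls of both genotypes enter alike. In control libraries the score was -0.88 ± 0.09 in WT and -0.42 ± 0.15 in KO (SD, n = 4), a difference of 0.46 with all 4 KO libraries above the highest WT library (exact two-sided permutation p = 0.0286, Benjamini-Hochberg 0.0477 over 10 tests of levels). That is 30.2% of the rise of 1.51 that WT neurons showed at 24 h. At 24 h the score was 0.63 ± 0.15 in WT and 0.63 ± 0.05 in KO, a difference of -0.0076 (exact permutation p = 0.943). The genes that rose were higher by 0.24 in KO controls and the genes that fell stood at -0.21 relative to WT (exact permutation p = 0.0286 each), while at 24 h the differences were -0.03 (p = 0.657) and -0.02 (p = 0.6), each by exact permutation. The late genes alone stood higher in KO in control cultures (5.12 ± 0.12 against 4.15 ± 0.18) and at 24 h (5.82 ± 0.04 against 5.41 ± 0.15), both with an exact permutation p of 0.0286. A shift of the untreated cultures and a smaller 24 h response share the same control libraries and are not separate evidence. Cell makeup and preparation of the cultures could give the same shift and were not tested.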
